A study of Homo sapiens with 12 samples.

How the data were processed

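Human dermal fibroblasts (HDF), the KDR-sorted cells made from them by lentiviral delivery of ER71/ETV2, and human umbilical vein endothelial cells (HUVEC) were profiled on Affymetrix PrimeView arrays, 12 arrays in all. The deposited values are log2 expression values per probeset made with Partek and RMA, per the submitters' processing notes; the versions are not given in the sources used here. RMA corrects background, brings the arrays of a run to a common distribution and summarises probes on the log2 scale, so a whole-array shift in RNA content cannot be read from such values and differences of dim genes are compressed. The arrays fall into 2 sets of 6 by the labels, each holding 2 HDF, 2 HUVEC and 2 KDR-sorted arrays. Array medians lay between 4.04 and 4.08 in set 1 and between 5.97 and 6.01 in set 2, so the deposited values of the sets were not on a common scale. Levels were therefore tested within a set, and the sets were compared through differences taken within each of them, except in 1 comparison that set long-term against day 7 levels directly.

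Probesets were named through the platform's probe table, with symbols checked against the NCBI RefSeq gene table of assembly GRCh38.p14. No genome build is given in the sources used here, so no coordinates are reported. Of 49395 probesets, 102 were Affymetrix controls, 44994 had 1 gene symbol, 1832 had several and 2569 had none; 44967 of those with 1 symbol had a gene ID in the RefSeq table. Probesets with several symbols or none were not named. XIST and Y-linked genes were left out. For the 11723 genes with more than 1 probeset, the probeset with the highest mean over the 12 arrays stood for the gene, which left 18106 genes.

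Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean for each of 6 groups, eBayes, two-sided moderated test). All 12 arrays entered 1 model, so that 6 residual degrees of freedom came from 6 groups of 2. P-values were adjusted by Benjamini-Hochberg over the 18106 genes, and a gene was called at an adjusted p under 0.05. Tables and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The comparisons were KDR-sorted cells against HDF and against HUVEC within each set, HUVEC against HDF within each set, and 2 differences of differences between the sets. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision; the median standard error of a difference within a set was 0.0976 on the log2 scale.

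There were 22 gene lists: endothelial surface and junction, endothelial and blood-endothelial transcription factors, arterial and Notch, venous, lymphatic endothelial, activated endothelium, blood cell, fibroblast identity and matrix, smooth muscle and myofibroblast, keratinocyte, melanocyte, neuronal and neural crest, pluripotency, cell cycle, cell cycle arrest and senescence, interferon response, TGF-beta targets, cholesterol synthesis, glycolysis and hypoxia, unfolded protein response, reference genes, and HOX genes. Some list members were not used here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were counted as called over all genes and, separately, adjusted over the list alone. Comparisons, lists and alternatives were fixed before the data were examined, as was the rule for naming genes. That rule took ETV2 and KDR first. For each comparison of KDR-sorted cells with HDF it took the 10 largest rises and 10 largest falls among called genes whose replicate values did not overlap, with up to 4 called members of each list. For the other comparisons it took 5 rises and 5 falls, with up to 2 called members of each list past camera. Other genes named in the text were chosen after their values were seen.

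The position of the sorted cells between HDF and HUVEC was described over genes that differed at least 2-fold between HUVEC and HDF in the other set. The log2 differences on both sides thus share no array, while the spread estimate behind the calls came from all 12 arrays. The share is a gene's log2 difference from HDF over its HUVEC minus HDF difference in the other set. The procedure was tested on simulated data in which 200 of 18106 genes were changed. For the day 7 comparison it recovered 12% of 50 genes changed 1.25-fold, 82% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, with 10 false calls among 17906 unchanged genes. For the long-term comparison the shares were 30%, 78%, 98% and 100%, with 6 false calls among 17906. Both simulations drew on the same spread estimates and changed few genes, while 44.6% and 47.1% of genes were called in the data. The adjusted threshold is therefore looser in the data, and the shares do not show a difference between the comparisons. Alternatives covered the spread estimate, the probeset rule, testing every probeset, a filter on dim genes, quantile normalization over all arrays, median centring, a fit within a set, the replicate number as a block, each array left out in turn, stricter thresholds, the reference of the time difference and of the position, and the inter-gene correlation. HUVEC as the reference for the lists and named genes of the time difference was added after seeing the data.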

Results

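Expression was measured on 12 arrays to ask how dermal fibroblasts that received ER71/ETV2 compare with the fibroblasts they came from and with an endothelial reference, soon after sorting and after long culture. ETV2 is an ETS-family transcription factor needed for the formation of blood and endothelial lineages. KDR, a receptor for vascular endothelial growth factor, was the surface marker used for sorting. Set 1 held KDR-sorted cells taken at day 7 with untransduced HDF and HUVEC. Set 2 held sorted cells kept in culture for up to 93 days, here called long-term cells, again with untransduced HDF and HUVEC. The labels give each set its own date, so that set, date and time in culture coincide. Each of the 6 groups had 2 arrays. The design text gives day 7 as the sorting day of all sorted cells, while the source name of 1 of the 2 long-term samples gives day 8. Values are log2 expression; group values are means ± SD (n = 2) and differences are log2 differences ± SE.

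The delivered factor and the sort marker were examined first, as a check of the labels. ETV2 was at 9.73 ± 0.05 in day 7 cells, 4.01 ± 0.29 in HDF and 3.84 ± 0.15 in HUVEC of set 1. In set 2 it was at 7.46 ± 0.05 in long-term cells, 5.54 ± 0.10 in HDF and 5.21 ± 0.18 in HUVEC. KDR was at 8.12 ± 0.14 in day 7 cells against 3.44 ± 0.30 in HDF and 7.38 ± 0.08 in HUVEC. In set 2 KDR was at 8.85 ± 0.04 in long-term cells, 4.73 ± 0.19 in HDF and 10.58 ± 0.06 in HUVEC. Both genes were higher in sorted cells than in HDF of the same set; because KDR was the gate, its difference is no finding. Replicate arrays correlated across genes at Pearson's r of 0.997 to 0.999, where genes are not independent replicates. Within set 1, the first principal component carried 62.8% of the variance and placed the day 7 arrays between HDF and HUVEC, while the second carried 34.5% and set the day 7 arrays apart from both. The same arrangement was seen in set 2, with 59.6% and 38.9%.

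Day 7 cells were compared with HDF to see what had changed early after delivery of the factor. No group was transduced without the factor. Effects of ETV2 therefore cannot be told apart from those of the viral delivery, the sort and the culture, here and in long-term cells. Transcription factors of the blood-endothelial lineage were among the largest rises: TAL1 went from 3.96 ± 0.15 in HDF to 12.73 ± 0.01, a difference of 8.77 ± 0.08, and LMO2, its partner in transcriptional complexes, from 3.07 ± 0.45 to 9.34 ± 0.01. Endothelial receptors rose as well, ROBO4 by 8.07 ± 0.10 and the angiopoietin receptor TEK by 6.45 ± 0.11. The other leading rises were HPSE, the heparan sulfate-cleaving heparanase, at 8.55 ± 0.13, the chemokines CXCL8 at 6.99 ± 0.07 and CXCL1 at 6.52 ± 0.21, the mannose receptor MRC1 at 6.59 ± 0.09, SHISA2 at 6.51 ± 0.16 and CYTL1 at 6.47 ± 0.14. The largest falls included 3 aldo-keto reductases, AKR1C2 at -7.02 ± 0.09, AKR1C1 at -6.85 ± 0.14 and AKR1C3 at -5.99 ± 0.18. They also included the matricellular protein gene CCN3 at -6.39 ± 0.10, the prostacyclin synthase gene PTGIS at -6.32 ± 0.06, MASP1 at -6.15 ± 0.19, EGFL6 at -5.76 ± 0.10, DPP4 at -5.39 ± 0.09, CHRDL1 at -4.93 ± 0.20 and MFAP4 at -4.91 ± 0.13. By limma, 8075 of 18106 genes were called, 4005 higher and 4070 lower, and 1272 and 1137 of these differed at least 2-fold. TAL1 had an adjusted p of 4.64e-12 and AKR1C2 of 2.06e-11 in limma's test.

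**Figure D1:**
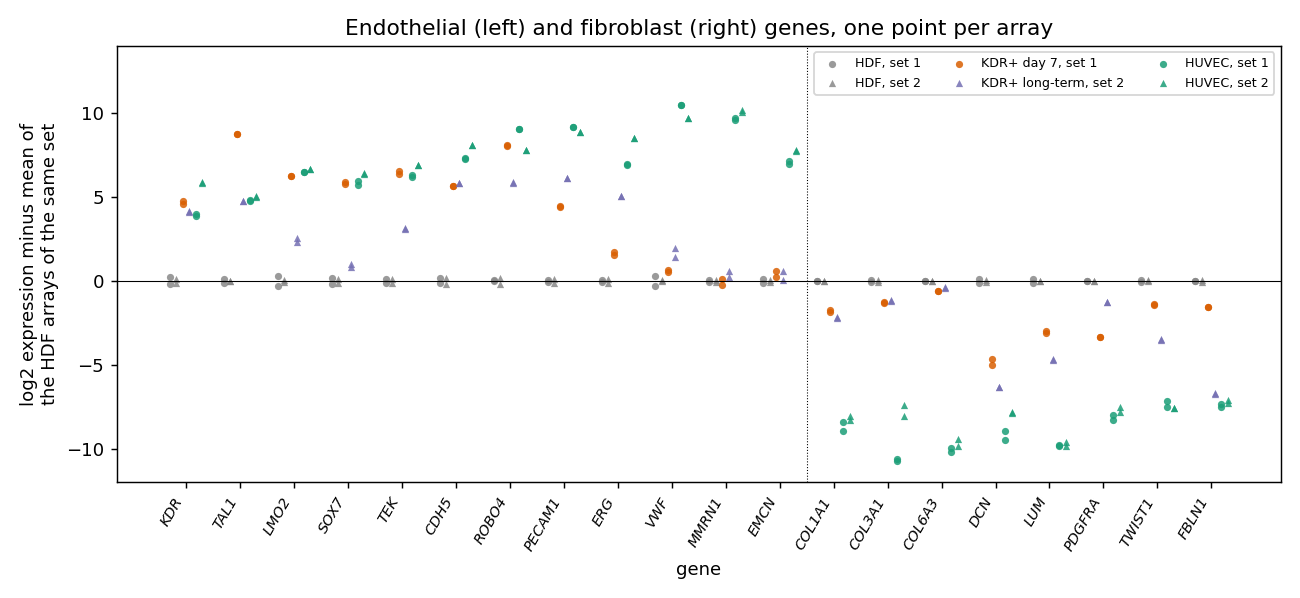
Log2 expression of 12 endothelial and 8 fibroblast genes (x axis) minus the mean of the HDF arrays of the same set (y axis), with 1 point for each of the 12 arrays, circles for set 1 and triangles for set 2. The genes were chosen after their values were seen; in day 7 cells TAL1 lies 8.77 above HDF while VWF lies 0.60 above, and COL6A3 lies near HDF at -0.58 in day 7 cells against -10.06 in HUVEC of set 1.

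The list of endothelial and blood-endothelial transcription factors rose at day 7, with a median log2 difference of 1.58. Of its 22 measured members 17 were called higher and 0 lower (17 and 1 adjusted over the list alone), including SOX7 at 5.84 ± 0.13 and SOX18 at 4.91 ± 0.15. Endothelial surface and junction genes rose with a median of 1.73, and 15 of 24 were called higher and 1 lower (15 and 1 adjusted over the list alone). Their leading members after ROBO4 and TEK were VE-cadherin, CDH5, at 5.67 ± 0.12 and ECSCR at 5.43 ± 0.11. Some members of the same list stayed near HDF: the difference was 0.60 ± 0.20 for VWF, -0.06 ± 0.14 for MMRN1 and 0.40 ± 0.17 for EMCN, of which only VWF was called; these 3 were chosen after their values were seen. Fibroblast identity and matrix genes fell with a median of -1.36, and 26 of 28 were called lower and 1 higher (27 and 1 adjusted over the list alone). DCN, encoding decorin, was at -4.83 ± 0.16, MFAP5 at -3.71 ± 0.17, DPT at -3.40 ± 0.10 and PDGFRA at -3.36 ± 0.11. In camera the adjusted p was 1.08e-11 for the fibroblast list, 6.5e-09 for the transcription factors and 2.01e-07 for the surface genes, and all of these calls held with an estimated correlation.

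Arterial and Notch genes were higher at day 7 by a median of 0.42, with 10 of 17 members called higher and 2 lower (10 and 2 adjusted over the list alone). The Notch target HES1 was at 4.91 ± 0.08, the BMP receptor ACVRL1 at 4.66 ± 0.09 and the ligand JAG1 at 2.57 ± 0.08, while the arterial ligand EFNB2 was at -3.40 ± 0.09. The list had an adjusted p of 0.00761 in limma's camera, which became an adjusted p = 0.079 with an estimated correlation. Glycolysis and hypoxia genes had a median of 0.51, with 10 of 17 called higher and 3 lower (10 and 3 adjusted over the list alone). Hexokinase HK2 was at 1.95 ± 0.10, PFKFB3 at 1.44 ± 0.07 and ALDOC at 1.19 ± 0.07, while ADM was at -2.12 ± 0.06. That list had an adjusted p of 0.0237 in limma's camera and an adjusted p = 0.106 with an estimated correlation. With the mean of probesets its median was 0.21 and the call was lost in limma's camera (adjusted p 0.063), as it was with dim genes left out (adjusted p 0.0555).

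The other 17 lists did not pass camera at day 7, but with the mean of probesets the arrest and senescence list (median 0.48, adjusted p 0.0431 in limma's camera) and the interferon list (0.15; 0.0401) did. In the arrest and senescence list (median 0.75, limma's camera adjusted p 0.0771), 8 of 14 members were called higher and 3 lower (9 and 4 adjusted over the list alone), with GDF15 at 4.30 ± 0.06, MMP1 at 3.80 ± 0.08 and MMP3 at -4.05 ± 0.09. In the interferon list (0.14; 0.0771), 11 of 24 were higher and 4 lower (11 and 4 adjusted over the list alone), with IFIT2 at 3.13 ± 0.09, MX1 at 1.76 ± 0.13 and ISG15 at 1.65 ± 0.06. Of 28 cell cycle genes 9 were higher and 6 lower (10 and 6 adjusted over the list alone), with a median of 0.08 and an adjusted p of 0.536 by limma's camera. The medians were 0.44 for venous, 0.06 for HOX, 0.39 for cholesterol synthesis, -0.02 for activated endothelium, 0.10 for lymphatic, 0.49 for TGF-beta and 0.20 for unfolded protein response genes, and -0.00 for reference genes. Among markers of other cell types, the medians were 0.02 for blood cell, -0.22 for smooth muscle, -0.12 for neuronal, 0.02 for keratinocyte, -0.03 for melanocyte and 0.07 for pluripotency genes. Single members did move: ICAM1 was at 3.81 ± 0.12, the venous-list receptor NRP2 at 4.18 ± 0.07, LAPTM5 at 4.15 ± 0.09, CD14 at 3.33 ± 0.12, DSP at 3.31 ± 0.10, PMEL at 3.32 ± 0.11, MITF at -3.03 ± 0.20, TUBB3 at -2.24 ± 0.09, SMAD6 at -3.24 ± 0.09 and the stress-induced factor ATF3 at 5.23 ± 0.13. The activated endothelium list had a mean of 1.36 and an upward test against its negative median, and the TGF-beta list a mean of -0.06 against its positive median and upward test. Melanocyte and reference genes had means of 0.02 and 0.03 against negative medians. Limma called none of the 7 pluripotency genes. HOXB3 was at 2.54 ± 0.14, but 1 of its 4 probesets was called in the opposite direction; EPHB4, at 0.31 ± 0.08, also had probesets called both ways, and the mean of its probesets gave -0.03.

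Long-term cells were compared with HDF of set 2 to see the state of the cells after extended culture. The receptor ADGRF5 stood at 13.31 ± 0.04 against 3.51 ± 0.03 in HDF, a difference of 9.80 ± 0.06, and the tight junction gene CLDN1 at 12.79 ± 0.03 against 3.84 ± 0.21. Further leading rises were VNN1 at 8.19 ± 0.15, the interferon-induced IFI27 at 7.57 ± 0.14, TM4SF18 at 7.42 ± 0.08, CD69 at 7.04 ± 0.10, the toll-like receptor TLR2 at 6.86 ± 0.12, HPGD at 6.63 ± 0.11, the acute-phase gene SAA1 at 6.62 ± 0.14 and MYCT1 at 6.60 ± 0.12. The largest falls were GAL, encoding galanin, at -7.34 ± 0.10, TMT1A at -6.88 ± 0.11, ALDH1A1 at -6.88 ± 0.09, OSR2 at -6.85 ± 0.13, the matrix gene FBLN1 at -6.69 ± 0.09, MEST at -6.69 ± 0.18, PTGIS at -6.60 ± 0.06, SELENOP at -6.59 ± 0.13, PTGFR at -6.46 ± 0.14 and DCN at -6.31 ± 0.16. By limma, 8520 genes were called, 4062 higher and 4458 lower, and 1164 and 1312 of these differed at least 2-fold. The adjusted p in limma's test was 2.29e-13 for ADGRF5 and 1.6e-11 for GAL.

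Cell cycle genes fell together in long-term cells, with a median of -3.42, and 25 of 28 were called lower and 0 higher (25 and 0 adjusted over the list alone). The mitotic genes KIF20A at -5.28 ± 0.16, TTK at -4.52 ± 0.15, CCNB2 at -4.31 ± 0.07 and BUB1 at -4.19 ± 0.12 led the list. Endothelial surface and junction genes rose by a median of 2.30, with 20 of 24 called higher and 1 lower (20 and 1 adjusted over the list alone). PECAM1 was at 6.15 ± 0.08, ROBO4 at 5.86 ± 0.10, CDH5 at 5.83 ± 0.12 and ECSCR at 4.42 ± 0.11, while EMCN was at 0.31 ± 0.17, not called, and CLEC14A at -0.27; EMCN and CLEC14A were chosen after their values were seen. Endothelial transcription factors had a median of 0.85, with 15 of 22 called higher and 3 lower (16 and 3 adjusted over the list alone). ERG was at 5.07 ± 0.09, TAL1 at 4.75 ± 0.08, SOX17 at 3.87 ± 0.11 and HHEX at 3.15 ± 0.06. Arterial and Notch genes rose by a median of 0.44, with 10 of 17 higher and 1 lower (10 and 1 adjusted over the list alone), including HES1 at 3.37 ± 0.08 and JAG1 at 2.21 ± 0.08. The adjusted p in limma's camera was 4.13e-17 for the cell cycle, 8.96e-11 for surface genes, 0.0013 for arterial genes and 0.000334 for transcription factors. The last became an adjusted p = 0.0879 with an estimated correlation.

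Genes of cell cycle arrest and senescence rose by a median of 1.25 in long-term cells, with 11 of 14 called higher and 2 lower (11 and 2 adjusted over the list alone). The members that moved most were secreted cytokines, IL1A at 6.25 ± 0.07, IL6 at 5.36 ± 0.21, IL1B at 5.34 ± 0.17 and the chemokine CXCL1 at 4.86 ± 0.21. Of the cyclin-dependent kinase inhibitors in the list, CDKN1A was at 1.31 ± 0.06, CDKN1C at -1.04 ± 0.07, CDKN2A at -0.28 ± 0.10 and CDKN2B at 0.29 ± 0.14, the last not called. Activated endothelium genes rose by a median of 1.76, with 7 of 9 higher and 1 lower (7 and 1 adjusted over the list alone). CXCL8 was at 6.07 ± 0.07, ANGPT2 at 5.18 ± 0.11, ICAM1 at 4.86 ± 0.12 and ESM1 at 4.41 ± 0.07. Interferon response genes rose by a median of 0.83, with 18 of 24 higher and 2 lower (18 and 3 adjusted over the list alone), including MX1 at 4.83 ± 0.13, CXCL10 at 3.22 ± 0.13 and IFI6 at 2.82 ± 0.08. Fibroblast genes fell by a median of -0.63, with 17 of 28 lower and 4 higher (17 and 4 adjusted over the list alone). Members fell unevenly: LUM was at -4.68 ± 0.11, THY1 at -3.51 ± 0.11 and COL3A1 at -1.17 ± 0.17, while POSTN was at 2.39 and COL1A2, not called, at 0.03; COL3A1, POSTN and COL1A2 were chosen after their values were seen. The adjusted p in limma's camera was 7.76e-06 for the arrest list and for the interferon list, 0.000155 for activated endothelium and 0.0017 for fibroblast genes, and these calls held with an estimated correlation.

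**Figure D2:**
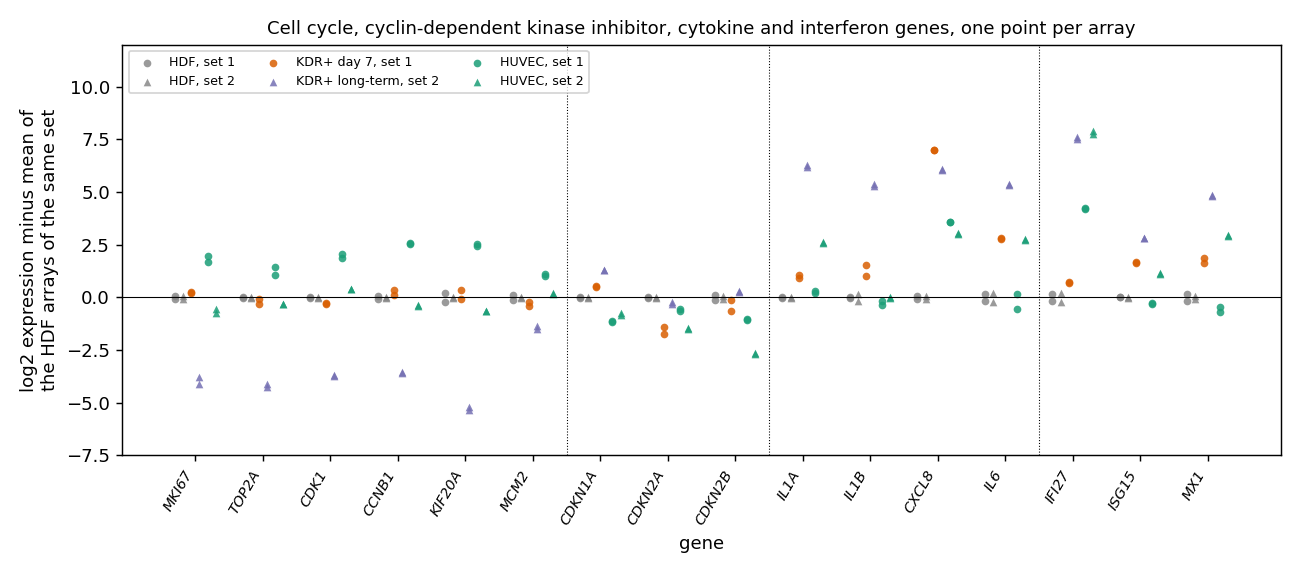
Log2 expression of 6 cell cycle, 3 inhibitor, 4 cytokine and 3 interferon genes (x axis) minus the mean of the HDF arrays of the same set (y axis), with 1 point for each of the 12 arrays, circles for set 1 and triangles for set 2. The genes were chosen after their values were seen; long-term cells lie below HDF and HUVEC of their set for KIF20A, at -5.28 from HDF, and above both for IL1B, at 5.34 from HDF.

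The other 14 lists did not pass camera in long-term cells. The smooth muscle and myofibroblast markers came closest, with a median of 0.32 and an adjusted p of 0.0501 by limma's camera. The list passed with the mean of probesets, at an adjusted p of 0.0288 in limma's camera, and with quantile normalization over the 12 arrays, at 0.0276; its adjusted p = 0.145 with an estimated correlation. Of these 15 genes 8 were higher and 3 lower (8 and 3 adjusted over the list alone), among them ACTG2 at 4.36 ± 0.10, TPM1 at 3.07 ± 0.07, CNN1 at 2.50 ± 0.17 and TAGLN at 2.28 ± 0.15. The medians were 0.35 for venous, 0.69 for TGF-beta, 0.11 for HOX, 0.18 for lymphatic, 0.15 for unfolded protein response, -0.02 for glycolysis and -0.08 for cholesterol synthesis genes, and 0.04 for reference genes. The remaining markers of other cell types had medians of 0.18 for blood cell, 0.26 for melanocyte, 0.13 for pluripotency, 0.09 for keratinocyte and 0.12 for neuronal genes. Means differed in sign from medians for glycolysis at 0.16, keratinocyte at -0.21, neuronal at -0.23 and reference genes at -0.04, and camera's direction followed the median for the last 2 and the mean for the others. Single members that were called included INHBA at 4.91 ± 0.09, TGFBI at 2.46 ± 0.08, CD14 at 3.88 ± 0.12, LAPTM5 at 3.42 ± 0.09, RELN at 3.56 ± 0.10, SLC2A1 at 2.03 ± 0.08, DNAJB9 at 2.10 ± 0.07, NRP2 at 2.14 ± 0.07 and DSP at -2.15 ± 0.10.

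**Figure D3:**
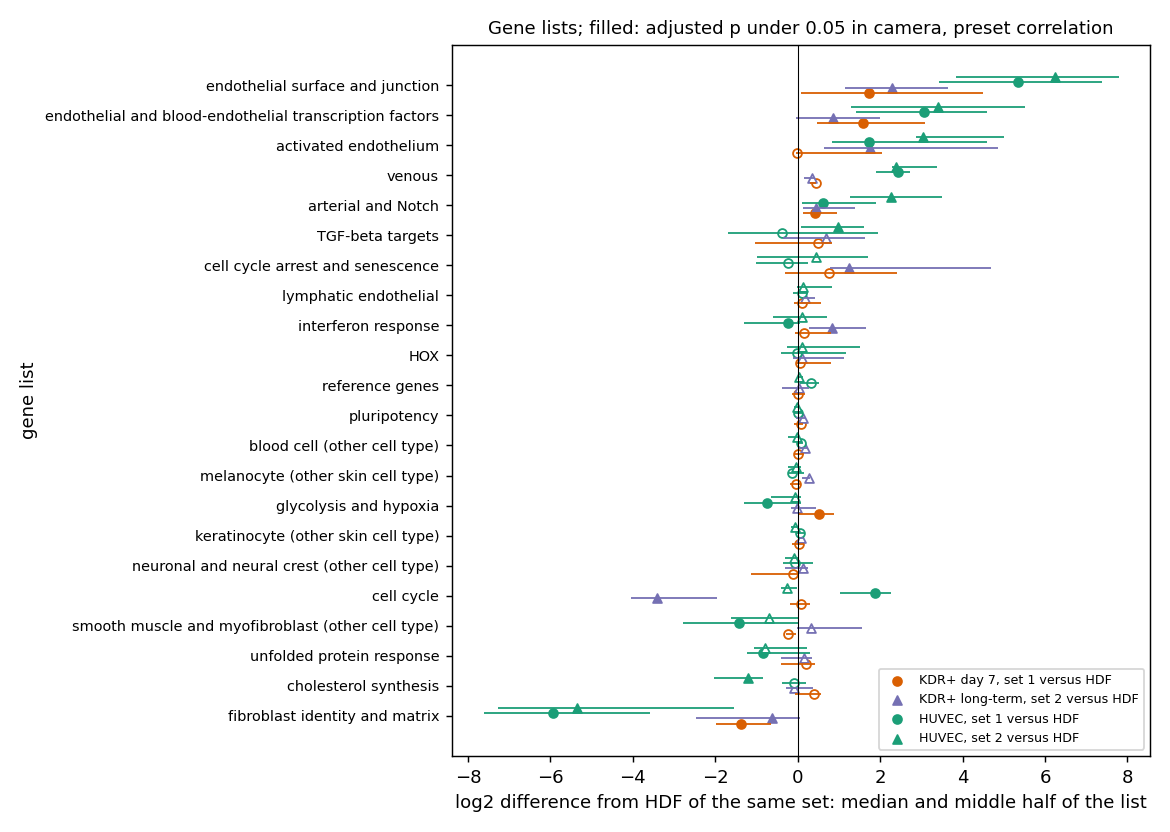
Median log2 difference from HDF of the same set (x axis, bars covering the 25th to 75th percentile of members) for the 22 gene lists (y axis), in day 7 cells and HUVEC of set 1 and in long-term cells and HUVEC of set 2. Filled symbols passed camera at the preset correlation; the cell cycle list lies at -3.42 in long-term cells and at 0.08 in day 7 cells, and the fibroblast list at -1.36 and -0.63 against -5.93 and -5.36 in HUVEC.

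HUVEC and HDF were compared in each set to give the reference for an endothelial state. In set 1 the largest differences towards HUVEC were VWF, encoding von Willebrand factor, at 10.47 ± 0.20, MMRN1 at 9.66 ± 0.14, PECAM1 at 9.14 ± 0.08, ROBO4 at 9.04 ± 0.10 and RGS5 at 8.84 ± 0.10. Those towards HDF were COL3A1 at -10.68 ± 0.17, COL6A3 at -10.06 ± 0.12, LUM at -9.82 ± 0.11, OSR2 at -9.55 ± 0.13 and CXCL12 at -9.38 ± 0.10. In set 2 the lead was taken by MMRN1 at 10.11 ± 0.14, VWF at 9.69 ± 0.20, MGP at 9.37 ± 0.08, PECAM1 at 8.88 ± 0.08 and CD93 at 8.72 ± 0.09, and on the HDF side by LUM at -9.69 ± 0.11, COL6A3 at -9.63 ± 0.12, SPON2 at -8.77 ± 0.13, ENPP2 at -8.62 ± 0.11 and TNC at -8.21 ± 0.10. By limma, 8134 genes were called in set 1 (4437 higher in HUVEC, 3697 lower) and 7875 in set 2 (3844 and 4031). Endothelial surface genes had medians of 5.34 and 6.25, with 23 of 24 higher and 0 lower in each set (23 and 0 adjusted over the list alone). Cell cycle genes were higher in HUVEC than in HDF in set 1, with a median of 1.88 and 27 of 28 higher and 0 lower (27 and 0 adjusted over the list alone; adjusted p of 8.25e-13 by limma's camera). In set 2 their median was -0.25, with 3 higher and 10 lower (3 and 10 adjusted over the list alone), and the list did not pass (adjusted p 0.219 in limma's camera). Fibroblast genes had medians of -5.93 and -5.36, with 28 of 28 lower in set 1 and 26 lower and 1 higher in set 2 (the same counts adjusted over the list alone). In camera 11 lists passed in set 1 and 8 in set 2, and 10 and 6 of them held with an estimated correlation. Those lost were the unfolded protein response in set 1 (adjusted p = 0.0736 with an estimated correlation) and in set 2 cholesterol synthesis (adjusted p = 0.092) and TGF-beta targets (adjusted p = 0.0583).

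Against HUVEC of set 1, day 7 cells had higher levels of fibroblast genes and lower levels of endothelial surface genes. COL6A3 was higher by 9.48 ± 0.12, COL3A1 by 9.39 ± 0.17, the collagenase MMP1 by 8.58 ± 0.08, IGFBP5 by 7.82 ± 0.10 and GREM1 by 7.51 ± 0.07. VWF was at -9.87 ± 0.20, MMRN1 at -9.72 ± 0.14, RGS5 at -9.09 ± 0.10, ICAM2 at -7.58 ± 0.16 and BMP6 at -7.10 ± 0.09. TAL1, at 12.73 ± 0.01, was above the HUVEC level of 8.73 ± 0.05, while ERG was at -5.31 ± 0.09. Limma called 8337 genes, 4005 higher and 4332 lower. Fibroblast genes were higher (median 4.76, 26 of 28 called higher and 0 lower, likewise adjusted over the list alone) and surface genes lower (median -3.16, 18 of 24 lower and 4 higher, likewise adjusted over the list alone). Cell cycle genes were lower by a median of -1.67, with 26 of 28 called lower and 0 higher (26 and 0 adjusted over the list alone); against HDF their median was 0.08, and HUVEC of this set lay above HDF by a median of 1.88. Of 22 lists 9 passed camera, and 8 held with an estimated correlation; the transcription factors, with a median of -0.43, had an adjusted p = 0.166 with an estimated correlation.

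Long-term cells were compared with HUVEC of set 2 in the same way. GREM1 was higher by 9.99 ± 0.07, SPON2 by 9.97 ± 0.13, COL6A3 by 9.22 ± 0.12, CLDN1 by 9.11 ± 0.12 and WNT5A by 8.44 ± 0.18. MMRN1 was at -9.73 ± 0.14, MGP at -9.31 ± 0.08, ADAMTS18 at -8.53 ± 0.07, RGS5 at -8.23 ± 0.10 and VWF at -8.00 ± 0.20. Limma called 8867 genes, 4348 higher and 4519 lower. Cell cycle genes were lower than in HUVEC too, by a median of -3.19, with 27 of 28 lower and 0 higher (27 and 0 adjusted over the list alone), including CDK1 at -4.11 ± 0.07. Surface genes had a median of -2.64, with 21 of 24 lower and 0 higher, and transcription factors a median of -1.72, with 21 of 22 lower and 1 higher, both likewise adjusted over the list alone; SOX7 was at -5.51 ± 0.13. Smooth muscle markers were higher by a median of 0.93, with 10 of 15 higher and 1 lower (10 and 1 adjusted over the list alone), TAGLN by 6.43 ± 0.15. Of 22 lists 12 passed camera and 10 held; cholesterol synthesis had an adjusted p = 0.0779 and the unfolded protein response an adjusted p = 0.0773 with an estimated correlation.

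The position of the sorted cells between HDF and HUVEC was described with the reference taken from the other set. Of 1285 genes at least 2-fold higher in HUVEC, 702 (54.6%) were called towards HUVEC in day 7 cells and 207 away from it, and the median share of the HUVEC difference was 0.213. Of 1201 genes at least 2-fold higher in HDF, 802 (66.8%) were called towards HUVEC and 168 away, with a median share of 0.371. In long-term cells 688 of 1321 HUVEC-higher genes (52.1%) were called towards and 387 away, with a median share of 0.200, and 703 of 1232 HDF-higher genes (57.1%) towards and 290 away, with a median share of 0.238. With the reference of the same set, which shares the HDF arrays, the long-term shares were 0.396 and 0.445. A simulated unchanged group gave 0.00214 and 0.00247. These long-term shares use another reference than the day 7 shares above and cannot be set against them.

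Genes called in both comparisons with HDF were then counted; these comparisons share no arrays. Day 7 and long-term cells had 1806 higher genes in common, where independent lists would share 898.5, and 2083 lower genes, where independent lists would share 1002.1. Genes called in opposite directions were 901 higher at day 7 and lower in long-term cells (986.1 from independent lists) and 789 the reverse (913.1 from independent lists). Among genes changed at least 2-fold the counts were 426 higher (81.8 from independent lists) and 440 lower (82.4 from independent lists). ROBO4, CDH5, TAL1, CXCL8 and GDF15 were higher at both times, and PTGIS, DCN and MASP1 lower at both.

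The difference between long-term and day 7 cells, each relative to HDF of its own set, was tested directly. Claudin CLDN1 led the genes higher in the later cells at 8.61 ± 0.17, followed by SORBS2 at 7.14 ± 0.22, IFI27 at 6.86 ± 0.20, LRRC17 at 6.73 ± 0.12 and VNN1 at 6.64 ± 0.21. The genes lower in the later cells were led by GINS4 at -7.32 ± 0.20, PTGS1 at -6.95 ± 0.08, GAL at -6.72 ± 0.14, MRC1 at -6.52 ± 0.12 and TFPI2 at -6.38 ± 0.09. SOX7 was at -4.93 ± 0.18 and TAL1 at -4.01 ± 0.11, and relative to HUVEC they were at -5.51 ± 0.18 and -4.27 ± 0.11, whereas ANGPT2 was at 5.21 ± 0.15. ETV2 was called lower in the later cells relative to either reference. Its mean level lay below the array medians in HDF and in HUVEC of both sets, so the size of its difference between the times rests on the background of each set and is not given. The same limit holds for the sizes of other genes that were dim in HDF, CLDN1 and TAL1 among them. For CDH5 the time difference was 0.16 ± 0.18, not called. Limma called 7859 genes, 3688 higher and 4171 lower. Cell cycle genes had a median of -3.54, with 24 of 28 lower and 1 higher, and interferon genes a median of 0.72, with 15 of 24 higher and 1 lower (24 and 1, and 16 and 1, adjusted over the list alone). These lists passed camera at either correlation. Relative to HUVEC in place of HDF, a reference chosen for the lists after the data were seen, the cell cycle median was -1.30, with 21 lower and 2 higher (22 and 2 adjusted over the list alone). Its adjusted p was 1.62e-07 by limma's camera and an adjusted p = 0.0503 with an estimated correlation. Interferon genes had a median of 0.14 and an adjusted p of 0.667 relative to HUVEC, so that call was lost, and IFI27 was at 3.26 ± 0.20. Time cannot be told apart from array set in this comparison except through the references, and 5254 genes were called in the same direction with HUVEC in place of HDF (1666.8 from independent lists) while 377 were called in opposite directions. These calls share the arrays of the sorted cells, from which part of the excess may come. The covariance of both differences across genes was 0.657. Simulated sorted cells kept at the HDF levels of their own set gave 0.0117, which shows only what the spread of the shared arrays adds. An effect of the set on the sorted cells alone would enter both differences too, so the covariance does not separate time from set. The HUVEC minus HDF difference itself, for which the labels name no difference but the set and its date, gave 5722 calls between the sets (2708 higher and 3014 lower in set 2). Of the 7859 time calls 40.9% were also called in that difference with the same sign, 3211 genes where independent lists would share 1245.9; the HDF arrays enter both, so part of the excess may come from them. Across genes the correlation of these differences was 0.401 and their covariance 0.246. Simulated sorted cells kept at the HDF levels of their own set gave 0.119 and 0.0123. That simulation shows only what the spread of the shared HDF arrays adds. It does not cover sorted cells that hold a constant position between HDF and HUVEC.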

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

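In this part the tests of a fast-dividing HDF culture, of a loss of dim signals, of background and of growth rates, and HUVEC as the reference of the lists and named genes, were chosen after the results had been seen; those of cyclin-dependent kinase inhibitors and of normalization were set beforehand. Results are given here because an effect differed between the sets under the same contrast, by limma's test of that difference, or because a signal lay in probesets outside the comparisons.

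Relative to HDF of their own set, long-term and day 7 cells differed in 7859 genes. The lists that moved were cell cycle at a median of -3.54, activated endothelium at 1.05, arrest and senescence at 0.98, interferon response at 0.72, smooth muscle and myofibroblast at 0.43 and endothelial transcription factors at -0.44. With an estimated correlation the adjusted p from limma's camera was 0.0118 for the cell cycle and 0.0456 for interferon, while it was 0.175 for activated endothelium and for arrest, 0.166 for smooth muscle and 0.192 for transcription factors. The sizes depend on the reference. Relative to HUVEC the medians were -1.30 for the cell cycle, -0.18 for activated endothelium, 0.66 for arrest, 0.14 for interferon, 0.46 for smooth muscle and -1.06 for transcription factors, and activated endothelium, arrest and interferon no longer passed limma's camera, with an adjusted p of 0.718, 0.161 and 0.667. Passing only relative to HUVEC in the main setting were arterial and Notch at -0.85, cholesterol synthesis at 1.03, glycolysis and hypoxia at -0.40 and fibroblast at -0.27. Relative to HDF their medians were 0.24, -0.16, -0.15 and 0.62, in the same order. With the mean of probesets the fibroblast list also passed relative to HDF (median 0.63, adjusted p 0.0258 in limma's camera). With an estimated correlation none of the 22 lists passed limma's camera relative to HUVEC, the lowest adjusted p being 0.0503. The named genes were CLDN1 at 8.61, SORBS2 at 7.14, IFI27 at 6.86, LRRC17 at 6.73, VNN1 at 6.64, GINS4 at -7.32, PTGS1 at -6.95, GAL at -6.72, MRC1 at -6.52 and TFPI2 at -6.38. All 10 were called with the same sign relative to HUVEC, among them CLDN1 at 8.91, SORBS2 at 4.92, IFI27 at 3.26, GAL at -4.17 and TFPI2 at -4.75. CLDN1 was dim in HDF of set 2 and HUVEC lay close to it, at -0.15 from HDF, so its sizes rest on the background of each set.

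For the fall of cell cycle genes in long-term cells, a fast-dividing culture of HDF alone as the whole cause is argued against by the comparison with HUVEC of the same set. There the list was also lower, at a median of -3.19. This does not cover the case that the HDF and HUVEC cultures of set 2 both divided fast. A loss of dim signals is argued against by the levels in HDF of set 2, where the 25 genes called lower had a median of 10.23 and 24 of them lay above the arrays' upper quartile of 8.30. Growth arrest of the long-term cells may account for it, but of 3 inhibitor genes only 1, CDKN1A, was called higher against both references; CDKN2A was higher than in HUVEC by 1.20 and at -0.28 against HDF, and CDKN2B was higher than in HUVEC by 2.95 and not called against HDF. Among inhibitors added after their values were seen, CDKN1B was at -1.75 against HDF and -2.04 against HUVEC. CDKN1C was at -1.04 against HDF and not called against HUVEC. Inhibitor transcripts do not decide between arrest and slow growth, so this stays open. Culture density and medium, which the labels do not give, stay open as well. Long-term cells were cultured for up to 93 days, and the labels give no time in culture for HDF and HUVEC. An effect of long culture or passage itself therefore cannot be told apart here.

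HUVEC minus HDF differed between the sets in 5722 genes, although the labels name no difference but the set and its date. The lists that moved were cell cycle at a median of -2.23, cholesterol synthesis at -1.75, arterial and Notch at 1.67, TGF-beta targets at 1.20, fibroblast at 1.00, endothelial surface at 0.53, interferon at 0.47, endothelial transcription factors at 0.42, glycolysis and hypoxia at 0.33 and activated endothelium at 0.32. With an estimated correlation 5 of these 10 were kept, and those lost had adjusted p from limma's camera of 0.0595 for cholesterol synthesis, 0.0512 for glycolysis, 0.0939 for surface, 0.106 for activated endothelium and 0.241 for transcription factors. With quantile normalization over 12 arrays the transcription factor median was 0.13 (adjusted p 0.201 in limma's camera) and that of activated endothelium 0.25 (0.121), and with the mean of probesets that of glycolysis was 0.18 (0.128), so these calls were lost there as well. The named genes were MMP1 at 6.10, IGFBP5 at 6.04, ACKR3 at 5.99, MEST at 5.69, IGFBP3 at 5.44, G0S2 at -6.33, IL13RA2 at -5.78, FKBP5 at -5.42, CCND2 at -5.05 and GPM6B at -4.76.

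Separate normalization of the sets as the whole cause of that difference is argued against, since after a common quantile normalization and 1 slope for the sets 4998 of the 5722 genes were called with the same sign. Background as the whole cause is argued against by 2998 genes above the upper quartile of their set in all 6 groups, of which 1542 were called. Cultures growing at different rates may account for part of it, but the cell cycle median of -2.23 prompted this explanation and so does not test it. Different donors or lots of cells and the date of each set stay open, as untested. Calls between long-term and day 7 cells carry the same kind of difference between sets.

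Among the 4305 probesets with no gene or several genes, which entered no comparison by gene, 349 differed at least 2-fold between day 7 cells and HDF, and 398 between long-term cells and HDF.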

How the results depend on the processing

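HUVEC as the reference for the lists and named genes of the time difference was chosen after seeing the data, and the other alternatives were planned. No count of called genes changed by over 1.5 times except as follows. Testing every probeset raised the counts, as it tests 49223 probesets in place of genes: 18198 for day 7 and 20789 for long-term cells against HDF, 18196 and 18755 for HUVEC against HDF in sets 1 and 2, 18733 and 21508 for day 7 and long-term cells against HUVEC, 18276 for the time difference and 12385 for the set difference of HUVEC minus HDF. Requiring a 2-fold change lowered them by construction, in the same order, to 2409, 2476, 2553, 2486, 2565, 2623, 3089 and 1587, and the overlaps to 426 and 440. The direct difference of long-term and day 7 cells with no HDF in it gave 17746 calls, 17302 of them higher, with a median of 1.47; it compares levels across sets that were not on a common scale, and the cause was not tested. With the same set as reference, the median shares of long-term cells were 0.396 for HUVEC-higher and 0.445 for HDF-higher genes; sharing the HDF arrays gave 0.00214 and 0.00247 in a simulated unchanged group, and the cause was not tested. With an estimated correlation the lists past camera fell from 5 to 3 at day 7, from 6 to 2 for the time difference and from 10 to 5 for the set difference. EPHB4 at day 7 turned to -0.033 as the mean of its probesets, which disagree.

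Replicate numbers share only a number: deviations of same-numbered arrays correlated between -0.035 and 0.1 across genes. Differences between replicates had an SD of 0.183 to 0.196 in set 1 and 0.141 to 0.152 in set 2. Fitting each set alone called 7087 genes at day 7 and 9134 in long-term cells against HDF. For HUVEC against HDF it called 7169 in set 1 and 8397 in set 2, the reverse of the main order. With the replicate block, 7939 genes were called at day 7 and 8424 in long-term cells against HDF. The block took the activated endothelium and arrest lists of the time difference to an adjusted p of 0.0502 in limma's camera, leaving 4 of 6 lists. Of named genes it ended the calls of APLNR at day 7, CD53 in long-term cells and KDR in the time difference, and it added ETV2 in HUVEC of set 2 against HDF. No called gene changed sign when any of the 12 arrays was left out. The lone array of its group was there assumed to vary like the others. Part of the calls of each comparison were lost in at least 1 of these fits. Their number is not given, since such a fit leaves 1 array in a group. Over the other results, 6665 values of named genes kept their side of the threshold, 57 lost the call and 5 gained it; for gene lists these were 854, 32 and 16. Signal over background limits dim genes: 13305 of 18106 genes had a mean above the table's median of 5.06 in at least 1 group. That median pools both sets and lies below the array medians of set 2. Genes dim in set 2 could thus pass, so the filter on dim genes did not remove all of them.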

Other observations

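The comparisons of this part with both references, the counts by list and the tests of a mixture were chosen after the data had been seen. Some genes lay outside the range between HDF and HUVEC. At day 7, 617 genes were at least 2-fold above both references of the set and 289 below both; in long-term cells 455 were above both and 593 below both. Of these genes 108 were above both at both times, where independent lists would share 15.5, among them CXCL1, CXCL8, IL1B, IL6, GDF15, ICAM1, CD14, ISG15 and MX1. Below both at both times were 77, where independent lists would share 9.5, among them PTGIS, AKR1C3, ALDH1A1, GATA6, SMAD6 and CDKN1B. Of 28 cell cycle genes, 23 were below both references in long-term cells, where 0.917 would be expected (adjusted p of 8.65e-29, Fisher's exact test). Above both in long-term cells were 8 of 24 interferon genes (adjusted p of 1.7e-06, Fisher's exact test), 6 of 14 arrest and senescence genes (6.79e-06) and 4 of 15 smooth muscle genes (0.00316), which were ACTG2, CNN1, TAGLN and TPM1. At day 7 they were 5 of 14 arrest and senescence genes, CXCL1, GDF15, IL1B, IL6 and MMP1 (adjusted p of 0.00154, Fisher's exact test), and 4 of 17 arterial and Notch genes, ACVRL1, DLL1, HES1 and JAG1 (0.0245). As whole lists against HDF, smooth muscle genes in long-term cells (adjusted p 0.0501) and arrest and senescence genes at day 7 (0.0771) did not pass limma's camera. Fisher's exact test treats members as independent; the arterial and Notch list as a whole had a median of -0.03 against HUVEC at day 7, with 6 higher and 7 lower (6 and 7 adjusted over the list alone), and EFNB2 was at -3.40 against HDF and -2.98 against HUVEC.

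HOX genes moved in both directions in long-term cells, and the list did not pass camera; the members named here from the HOXC cluster were chosen after their values were seen. Differences from HDF were 4.77 ± 0.14 for HOXB3, 4.65 ± 0.13 for HOXB7, 3.77 ± 0.15 for HOXB6 and 3.48 ± 0.20 for HOXB5, while HOXC8 was at -2.30, HOXC4 at -1.73 and HOXC6 at -1.72. In HUVEC of the same set HOXB3 was at 5.32 and HOXB7 at 5.09 against HDF, and HOXC8 at -1.70. HOXB6 and HOXB5 were only at 1.54 and 1.48 there, below their differences in long-term cells. At day 7 the differences were 2.54 ± 0.14 for HOXB3, 0.33 for HOXB7, which was not called, and 1.07 for HOXC8.

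Endothelial genes approached HUVEC very unevenly, and a mixture of unchanged HDF and HUVEC-like cells could produce intermediate values. The sort on KDR, at 3.44 in HDF of set 1 and 8.12 in day 7 cells, selects against unchanged HDF. Its purity is not given, and long-term cells were cultured on after it, so the sort does not settle the matter. A mixture of unchanged HDF and HUVEC-like cells implies the same share of HUVEC-like cells for each gene on the linear scale. In day 7 cells 8.57% of 35 endothelial list genes gave a share within 2-fold of the median share, and in long-term cells 35.1% of 37 did. Within 4-fold lay 10 of 35 genes at day 7 and 24 of 37 in long-term cells. Shares over 100% were implied by 6 genes at day 7 and 0 in long-term cells, and shares under 1% by 9 and 6. The day 7 values argue against that mixture as the whole cause. For long-term cells the outcome depends on the window, which was chosen after the data were seen, so it is not decided. A mixture that holds cells of other states stays open, since the arrays average over cells.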
